A study of Homo sapiens with 6 samples.

How the data were processed

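RNA was measured in 6 libraries of LNCaP, a human prostate cancer cell line that responds to androgen. Per the labels, 3 libraries came from control cells and 3 from cells kept for 1 week in 0.5 µM palbociclib. Palbociclib inhibits the cyclin-dependent kinases CDK4 and CDK6. No dose or culture time is recorded here for the controls. Libraries were made from total RNA with oligo-dT beads, per the labels' protocols, so that transcripts without a poly(A) tail are under-represented. Whether the kit or the counting kept strand is not given in the sources used here, so that reads of genes overlapping on opposite strands cannot be told apart.

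The deposited table holds an estimated count and an FPKM value (fragments per kilobase of exon, scaled to mapped fragments) for each of 35430 genes in each library. Per the submitters' processing notes, reads were trimmed with cutadapt 1.9, aligned to hg38 with HISAT2 2.0.4, and assembled and quantified with StringTie 1.3.4d, and edgeR was used for the authors' own comparison. The series' design text names fastp in place of cutadapt for trimming. It also states that the assemblies of the samples were merged before quantification. The annotation release behind the deposited table is not given in the sources used here. The deposited estimated counts were already whole numbers, so that rounding to whole numbers before the test changed no value. Counts of 4, 8 and 12 were more frequent than their neighbours in every library. A single fragment inside a gene therefore adds about 4 to its deposited count, and the counts overstate the number of fragments by about that factor. For 10044 genes above 500 counts in every library, count and FPKM as deposited by the authors implied a single length per gene within 1.65% across libraries. No deposited row lacked a gene, and 0 columns of per-sample values were left without a sample.

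Totals ran from 57082715 to 78117945 estimated counts per library, with about 4 counts to a fragment. The floor used for genes at 0 in a whole group was 12 counts per library (3 fragments), equal to 0.148 to 0.211 CPM (counts scaled to a library of fixed total). Floors cover counting error only, since amplified fragments carry no molecular identifiers. Libraries of a group differed by more than sampling noise in every pair: chi-square per degree of freedom on counts divided by 4 ran from 3.187 to 5.703. No library was therefore treated as a repeat of another.

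The comparison was palbociclib minus control with all 6 libraries. Genes were kept by edgeR's filterByExpr with a minimum count of 10 and a minimum total of 15, which left 21218 genes and removed 14212. Counts were scaled by the trimmed mean of M-values (TMM), and fold changes were tested with edgeR's quasi-likelihood F-test with Benjamini-Hochberg adjustment over all genes tested, with a threshold of 0.05. Standard errors (SE) are the absolute log2 fold change divided by the square root of the F statistic. Levels are TMM-scaled CPM with the standard deviation (SD) over 3 libraries. The series' labels number the replicates in both groups, but nothing says that equal numbers share a culture or a day, so the fit had no replicate block.

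A set of 35 gene lists, the test for each result and the rule for named genes were fixed before the data were examined. The lists covered the cell cycle, growth, senescence, plasticity, prostate identity, ferroptosis, stress responses, metabolism, immune signalling, RNA quality and markers of other cell types. Heat shock proteins and immediate early genes were set as lists of sample handling. Lists were tested with limma's camera at a preset inter-gene correlation of 0.01 on log2 CPM with a prior count of 2, with Benjamini-Hochberg adjustment over the lists with 5 or more tested members. Camera with an estimated correlation and limma's fry were run beside it. The rule named the 8 largest rises and the 8 largest falls among genes past the threshold with a mean of at least 5 CPM and groups that did not overlap. Unnamed loci, clone names and Y-linked genes were left out of that part. The rule also named 10 genes of the series title and of the drug's target pathway whatever their result, and up to 4 members of each list with the lowest adjusted p. Members of further annotation terms were named by the same count of 4, and list members that did not pass could be given as values. Some genes that the rule named are not reported here. Genes named outside that rule are said to have been chosen after their values were seen.

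Coordinates are those of GENCODE 44 on hg38. Of the gene identifiers in the table, 35399 were found in that release and 29552 had the same start and end there. Exons of 7976 listed genes overlapped those of another listed gene that had at least 60 counts over the libraries. Among the genes named by the rule, such overlap touched DNAH8, BEST1, FTH1, COL16A1, SLC6A9, SLC7A11, CDK4, CCND1, PRIM1, MCM7, FOXM1, KIF2C, CDKN1A, BRCA1, CHEK1, TP53INP1, TMPRSS2, ITGA6, PEG10, COL5A1, CD68, THBS1, ITGB1, SLC1A5, FADS2, TFRC, PCBP2, PRDX1, ASNS, FDFT1, IDI1, ATP5PB, NDUFA2, ATP6V1A, PSME2, PDIA3, CFLAR, IRF1, HSP90AA1, HSPA8, RPL10, NOC2L, MT-ND4 and MT-ATP6, and their levels are uncertain to that extent.

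Alternatives fixed beforehand were edgeR's RLE factors, library size with no composition factor, DESeq2, no filter on low counts, a filter of 10 counts in at least 3 libraries, the replicate number as a block, limma on log2(FPKM + 1) and on log2(FPKM + 0.1), each library left out in turn, other thresholds and other set tests. Fold changes on the FPKM scale understate changes of low genes. Alternatives added after seeing the data were counts divided by 4, a minimum count of 40, control library 3 alone as the control group, mitochondrially encoded genes left out, and genes with overlapping exons left out. With a single control library, that library was assumed to vary like the palbociclib libraries.

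The fits were tested on simulated data: 5 sets of counts drawn from the means and library sizes of this comparison, each with 200 genes changed by known folds. With a spread drawn per gene, over 20521 genes on average, edgeR recovered 37.2% of changed genes at a fold of 1.5, 58.3% at 2, 74.0% at 4 and 92.4% at 8, and 10.2% of its calls were false. With a spread that followed the expression trend, over 20571 genes, recovery was 44.9%, 58.6%, 86.4% and 96.2% at these folds, and 4.12% of calls were false. DESeq2 gave 24.4% and 16.7% false calls in the same sets, and limma on log2 values 10.7% and 5.46%. Among 20 simulated lists, the 2 shifted by 1 log2 unit were called and 0 others were. The simulated genes varied independently, so these lists lacked any correlation between members and do not give camera's false calls for real lists.

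Software was R 4.3.3, edgeR 4.0.16, limma 3.58.1, DESeq2 1.42.0, Python 3.11.15 and matplotlib 3.10.9.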

Results

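Polyadenylated RNA of LNCaP, an androgen-responsive human prostate cancer line, was sequenced in 3 control libraries and in 3 libraries of cells treated for 1 week with 0.5 µM palbociclib, which inhibits CDK4 and CDK6, the kinases that release the retinoblastoma brake on S phase. Control libraries 1, 2 and 3 held 78117945, 57082715 and 60596052 estimated counts, and palbociclib libraries 1, 2 and 3 held 76211410, 67286048 and 59183323. About 4 of these counts correspond to a single fragment. The design implies a single comparison, palbociclib against control. No culture time is recorded here for the controls, so that time in culture cannot be told apart from the drug. Per the series title, its question was whether the drug lowers TRIB3 and, through SOX2, SLC7A11, the cystine importer that protects cells from ferroptosis, an iron-dependent death by lipid peroxidation.

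The amino acid stress programme run by the transcription factor ATF4 fell after 1 week of palbociclib: of 43 ATF4 targets tested, 41 were lower and 1 was higher, with a median log2 fold change of -1.63 (3 libraries per group). TRIB3, a pseudokinase that this programme induces, fell 10.5-fold, and SLC7A11, which exchanges glutamate for cystine, fell 6.57-fold. Androgen-regulated genes, cholesterol synthesis enzymes and heat shock chaperones rose, with medians of 0.69, 0.76 and 0.78 on the log2 scale. Replication-dependent histone genes were higher too (median 0.70), while mitosis genes were lower by a smaller amount (median -0.32, camera adjusted p = 1.92e-06, and adjusted p = 0.115 with an estimated correlation). Across the transcriptome, 4270 genes were higher and 3921 lower of 21218 tested (edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, threshold 0.05).

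Of these, 636 rose and 1118 fell by more than 2-fold. Groups did not overlap for 51.1% of tested genes, where chance alone gives 10% for 3 against 3. The leading principal component held 47.8% of the variance and separated the groups. Higher genes made up 52.1% of the calls with TMM scaling, 36.1% with library size alone and 37.6% with limma on log2(FPKM + 1). Library size alone moved the median of all genes by -0.11 log2 units, so that changes smaller than this depend on the scaling. Nothing says that the replicates came from separate cultures, and p-values then measure only the spread between these libraries, which may be technical.

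**Figure D1:**
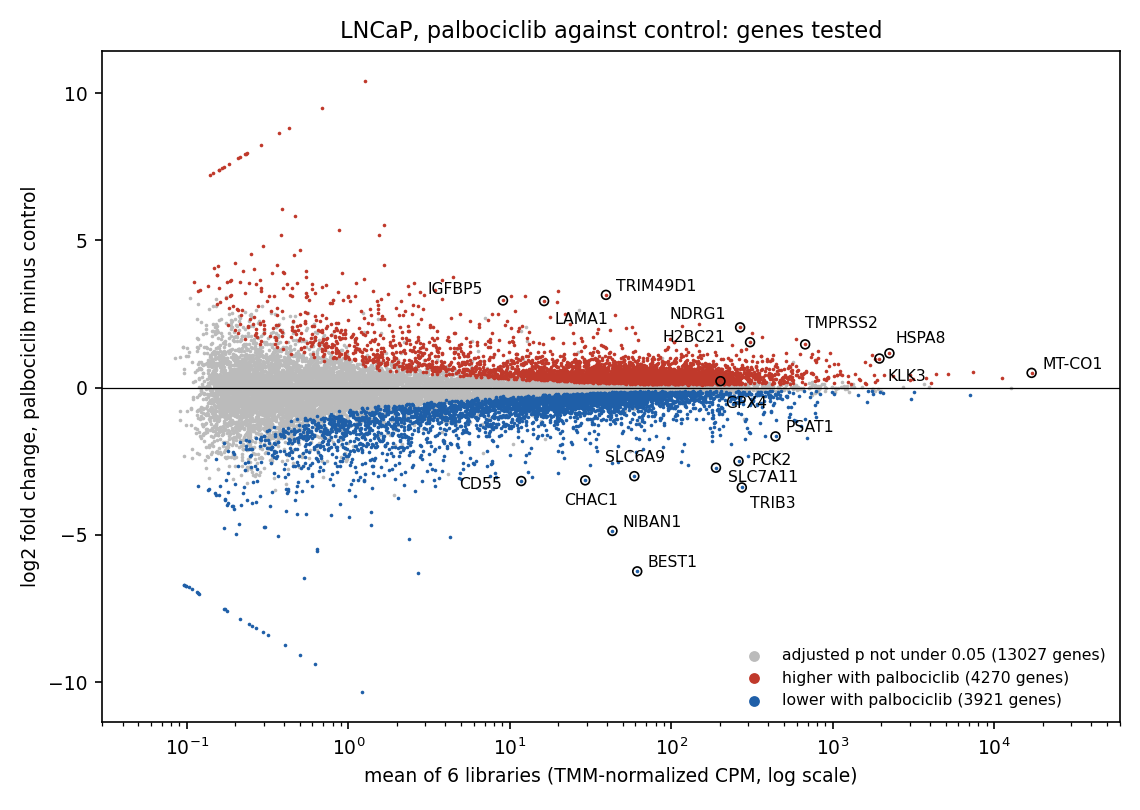
Each point is a gene tested, with its mean level over 6 libraries (TMM-normalized CPM, log scale) on the horizontal axis and its log2 fold change, palbociclib minus control, on the vertical axis; red and blue mark the 4270 higher and 3921 lower genes and open circles mark 19 labelled genes. TRIB3 sits at -3.39 and SLC7A11 at -2.72, below 0, and KLK3 at 0.99 and TMPRSS2 at 1.47, above it.

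TRIB3 (ENSG00000101255, chromosome 20, 362835 to 397559 on hg38, as are all positions) went from 499.6 ± 21.7 CPM in controls to 47.7 ± 2.91 with palbociclib (SD, n = 3 each), a log2 fold change of -3.39 ± 0.0579 (SE; edgeR adjusted p = 1.52e-08). SLC7A11 (ENSG00000151012, chromosome 4, 138164097 to 138242349) went from 328.6 ± 47.7 to 50 ± 1.601 CPM, a log2 fold change of -2.72 ± 0.0957 (edgeR adjusted p = 2.63e-07). Its exons overlap the antisense gene SLC7A11-AS1 over 865 of 9645 bases. That gene was at 2.41 CPM in controls and 0.383 CPM with palbociclib, and reads of the shared bases cannot be told apart. SOX2 (ENSG00000181449, chromosome 3, 181711925 to 181714436), a pluripotency transcription factor, had 4 counts in control library 1 and 0 in each of the other libraries, all below the floor of 12. It was not tested, and no change of SOX2 was detectable at this depth.

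GPX4 (ENSG00000167468, chromosome 19, 1103994 to 1106779), the peroxidase that reduces lipid peroxides, was at 186.3 ± 2.29 CPM in controls and 217.4 ± 17.03 with palbociclib (log2 fold change 0.22 ± 0.0557, edgeR adjusted p = 0.0123). That call was lost with library size alone (adjusted p = 0.149), against control library 3 alone (0.142) and without palbociclib library 2 (0.0513), over a range of 0.00033 to 0.17 among alternatives. ACSL4 (ENSG00000068366, chromosome X, 109624244 to 109733403), which loads polyunsaturated fatty acids into membranes, rose from 11.9 ± 1.24 to 19.4 ± 1.42 CPM (log2 fold change 0.71 ± 0.106, edgeR adjusted p = 0.00084). Of the drug's targets, CDK6 (ENSG00000105810, chromosome 7, 92604921 to 92833917) fell from 16.4 ± 3.38 to 8.86 ± 0.244 CPM, a log2 fold change of -0.89 ± 0.147 (edgeR adjusted p = 0.00148). CDK4 (ENSG00000135446, chromosome 12, 57747727 to 57756013), whose exons overlap TSPAN31 over 1369 of 3094 bases, was at 174 ± 6.93 and 198.2 ± 3.81 CPM (0.19 ± 0.0411, edgeR adjusted p = 0.00645); the call ended with library size alone (adjusted p = 0.186, range 0.000145 to 0.186). Cyclin D1 (CCND1, ENSG00000110092, chromosome 11, 69641156 to 69654474), the activator of both kinases, rose from 249.2 ± 3.33 to 335.2 ± 22.8 CPM (0.43 ± 0.0505, edgeR adjusted p = 0.000209). RB1 (ENSG00000139687, chromosome 13, 48303744 to 48599436), their main substrate, had 44.2 ± 3.41 and 44.5 ± 1.49 CPM (0.01 ± 0.0642, edgeR adjusted p = 0.921).

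**Figure D2:**
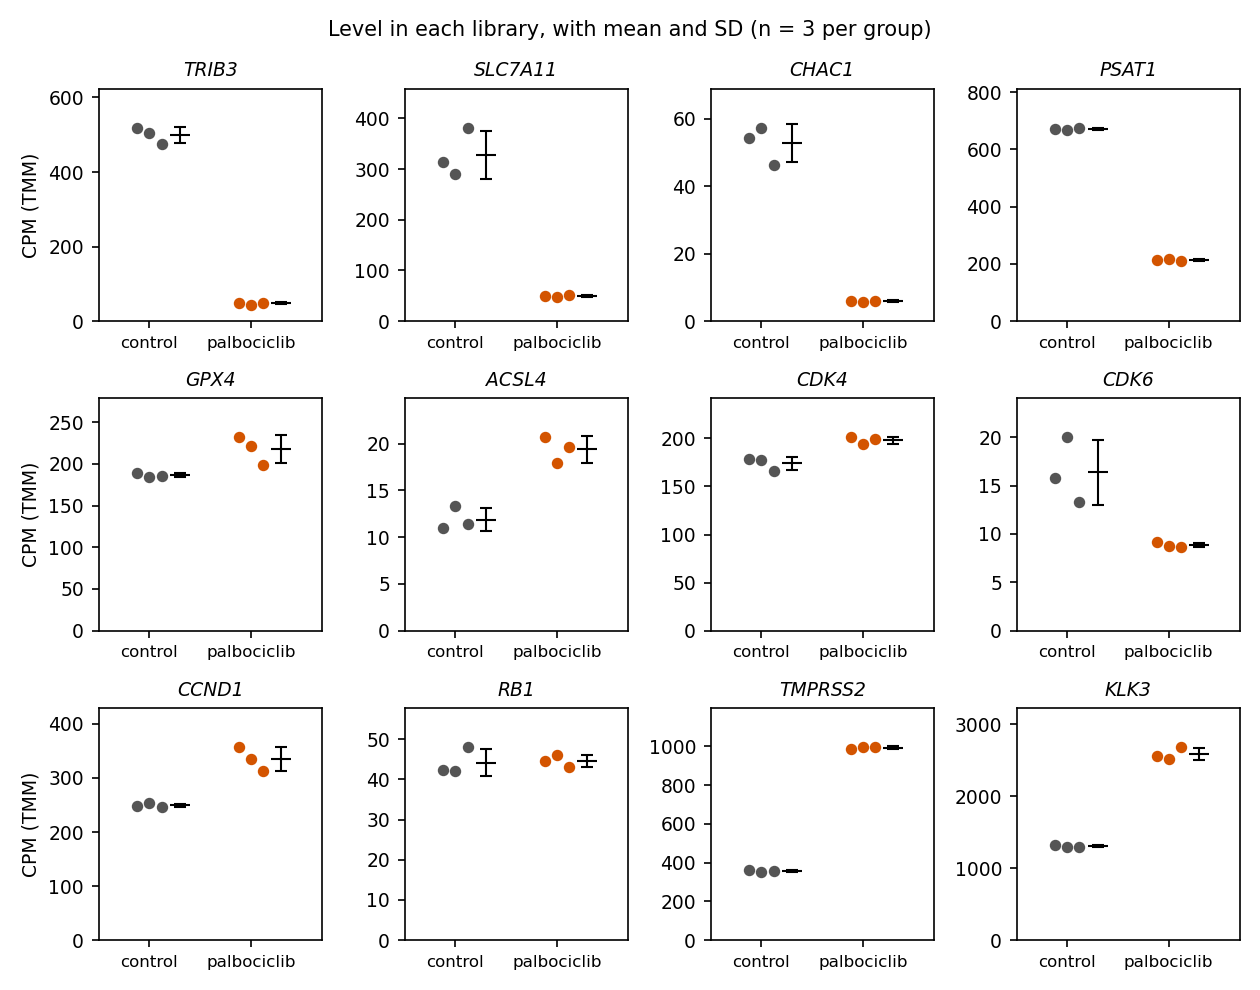
TMM-normalized CPM (vertical axes, from 0) of 12 genes in each library, with the mean and SD of 3 libraries per group beside the points; grey is control and orange palbociclib. TRIB3, SLC7A11, CHAC1 and PSAT1 are lower in every palbociclib library than in any control library, while RB1 overlaps between the groups.

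The 8 largest falls among well-measured genes were led by BEST1, a calcium-activated chloride channel (121.6 ± 14.6 to 1.596 ± 1.149 CPM, log2 fold change -6.24 ± 0.341, edgeR adjusted p = 2.51e-06). BEST1 shares 1267 of its 8688 exon bases with FTH1 on the opposite strand. FTH1, the ferritin heavy chain, fell by 0.86 log2 units, and the split of reads between them is uncertain. NIBAN1, a stress-induced protein, fell from 83.6 ± 2.69 to 2.88 ± 0.304 CPM (-4.86 ± 0.0826, edgeR adjusted p = 1.52e-08). After TRIB3 followed CD55, which shields cells from complement (-3.17), CHAC1, which degrades glutathione (52.7 to 5.96 CPM, -3.15), COL16A1, a collagen chain (-3.02), and SLC6A9, a glycine transporter (-3.00). SERPINA1, the protease inhibitor alpha-1-antitrypsin, was also among them (-3.05 ± 0.65, edgeR adjusted p = 0.00566), but its level was 15.1, 25.9 and 2.79 CPM in control libraries 1, 2 and 3. Against control library 3 alone it was at -0.67 (adjusted p = 0.132, range 3.16e-05 to 0.132).

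The 8 largest rises began with TRIM49D2 (3.30 ± 0.148, edgeR adjusted p = 8.32e-07) and TRIM49D1 (3.15), near-identical copies on chromosome 11 between which the division of reads is uncertain. DEFB132, a beta-defensin gene, rose from 2.54 ± 0.0774 to 22.2 ± 0.79 CPM (3.13 ± 0.0994, edgeR adjusted p = 1.65e-07). IGFBP5, which binds insulin-like growth factors, rose from 2.06 to 16.1 CPM (2.96), and LAMA1, a laminin chain of basement membranes, from 3.75 to 28.9 CPM (2.94). The long non-coding RNA LINC00161 (2.92), GRIN3A, a glutamate receptor subunit (2.59), and DNAH8, an axonemal dynein (2.50), completed the group.

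Counts per list are by edgeR over all genes tested, and set tests are by camera. Members named as exceptions to their list's direction, FGF21 and SLC7A11-AS1 were picked after their values were seen. At the preset correlation camera also called 8 to 13 lists in every split of the libraries that mixed the groups. Such splits keep part of the difference between the groups, so they do not give a rate of false calls. The 41 ATF4 targets that fell, also 41 when adjusted over the list alone, gave a camera adjusted p = 1.19e-24, and adjusted p = 0.0329 with an estimated correlation. They included enzymes of serine and asparagine synthesis, PSAT1 (671.7 ± 3.67 to 213.5 ± 1.95 CPM, -1.65) and ASNS (-1.91), and PCK2, the mitochondrial phosphoenolpyruvate carboxykinase (-2.49). ATF4 itself, named after its value was seen, fell from 905 ± 16.04 to 369.8 ± 8.80 CPM (-1.29 ± 0.0352, edgeR adjusted p = 7.48e-08). FGF21, a stress hormone, had 168, 155 and 163 counts in controls and 0 in every palbociclib library, at least 13.0-fold lower against the floor of 12 counts per library, and with that bound the list's median was also -1.63. The exceptions were ALDH18A1, a proline synthesis enzyme, at 0.14, and VLDLR at -0.07, which did not pass.

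Of 25 genes of cystine import and glutathione, 15 fell, 9 rose and 1 did not pass, the same counts when adjusted over the list alone (median -0.62, camera adjusted p = 0.00302; adjusted p = 0.101 with an estimated correlation). The falls were led by PSAT1, CTH, which makes cysteine from cystathionine (-1.98), CHAC1 and the glutamine carrier SLC1A5 (-1.61); SLC7A11, PSAT1, CTH and CHAC1 are also ATF4 targets. Members that rose included GPX2 (1.46) and GGT1 (1.03). Among 36 other ferroptosis regulators 15 were higher and 5 lower, or 16 and 6 when adjusted over the list alone. Their median was 0.10 (camera adjusted p = 0.035, and adjusted p = 0.173 with an estimated correlation), and the call ended without control library 3 (adjusted p = 0.0752, range 3.78e-05 to 0.173). The desaturase genes FADS2 (1.02) and SCD (0.95) and the elongase ELOVL5 (0.93) rose there, while the median turned to -0.01 with library size alone and was 0.17 against control library 3 alone. Iron handling genes gave no list call (10 higher, 9 lower of 26; 12 and 9 when adjusted over the list alone; median 0.05, mean -0.10, -0.07 with library size alone, camera adjusted p = 0.542). TFRC, the transferrin receptor, rose from 166.8 ± 7.03 to 413 ± 7.80 CPM (1.31), FTH1 fell (-0.86), and so did PCBP2 (-0.52) and the metal importer SLC39A14 (-0.48).

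Among stress lists, NRF2 targets were split, with 9 higher, 10 lower of 31, or 9 and 13 when adjusted over the list alone. Their median was -0.04, or 0.04 against control library 3 alone (camera adjusted p = 0.75), with a rise of the peroxidase PRDX1 (1.15) and the drug exporter ABCC4 (0.63). Targets of XBP1 and ATF6 in the unfolded protein response were split as well, with 9 higher, 10 lower of 31, or 9 and 11 when adjusted over the list alone. Their median was -0.02 (camera adjusted p = 0.489). The sensor ERN1 (-1.19) and XBP1 (-1.29) fell, whereas the chaperones HSPA5 (0.45) and CALR (0.56) rose. Of 29 p53 targets 9 rose and 11 fell, or 9 and 13 when adjusted over the list alone. Their median was -0.04 (camera adjusted p = 0.476). TP53INP1 (0.90), BTG2 (0.53) and the CDK inhibitor CDKN1A (0.47) rose, while SESN2 (-2.02) and GDF15 (499.4 ± 35.9 to 101.1 ± 21.5 CPM, -2.30), which ATF4 also drives, fell. Heat shock proteins rose in 18 of 20 cases, also 18 when adjusted over the list alone. Their median was 0.78 (camera adjusted p = 7.11e-10, and adjusted p = 0.0428 with an estimated correlation). That list had been set beforehand under sample handling, and a difference in handling between the groups was not tested. HSPA8, the constitutive cytosolic chaperone, went from 1383 ± 40.3 to 3111 ± 33.5 CPM (1.17), HSP90AA1 from 583 to 1333 CPM (1.19), and the co-chaperone DNAJA1 rose by 1.24.

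Androgen-regulated genes were higher in 29 of 40 cases and lower in 4, or 29 and 5 when adjusted over the list alone (median 0.69, camera adjusted p = 3.37e-09, adjusted p = 0.0428 with an estimated correlation). Leaving out genes with overlapping exons moved the median to 0.39. KLK3, which encodes prostate-specific antigen, rose from 1304 ± 13.3 to 2592 ± 86.5 CPM (0.99 ± 0.0352, edgeR adjusted p = 2.63e-07), the protease TMPRSS2 by 1.47 and NDRG1, a differentiation- and hypoxia-linked gene, by 2.05. The 4 that fell were UGT2B15 (-1.94) and UGT2B17 (-1.28), which inactivate androgens by glucuronidation, FOLH1 (-0.29), which encodes prostate-specific membrane antigen, and the kinase MAK (-0.48). UGT2B15, UGT2B17 and FOLH1 are known to be repressed by androgen. Of 20 luminal epithelial genes 12 rose and 4 fell, also 12 and 4 when adjusted over the list alone (median 0.27, or 0.16 with library size alone, camera adjusted p = 0.0126, adjusted p = 0.115 with an estimated correlation). The acid phosphatase ACP3 rose by 1.48, against a fall of the epithelial splicing factor ESRP1 (121.6 to 39.3 CPM, -1.63).

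Cholesterol synthesis and uptake genes rose in 21 of 25 cases with 0 lower, the same when adjusted over the list alone (median 0.76, camera adjusted p = 8.37e-10, adjusted p = 0.0428 with an estimated correlation). Among them were HMGCS1 (1.22), which makes HMG-CoA at the pathway's entry, IDI1 (1.05), and FDFT1 (1.08), which makes squalene. Fatty acid synthesis genes were higher in 17 of 25 and lower in 3, or 18 and 3 when adjusted over the list alone. Their median was 0.46 (camera adjusted p = 4.33e-05, and adjusted p = 0.0588 with an estimated correlation), with ELOVL7 at 1.11. Glycolysis and hypoxia genes rose in 26 and fell in 5 of 32, the same when adjusted over the list alone (median 0.44, camera adjusted p = 7.68e-07, adjusted p = 0.115 with an estimated correlation). Lactate dehydrogenase LDHA (0.95) and the carbonic anhydrase CA12 (1.73) rose. The falls were the angiogenic factor VEGFA (-1.07), ENO2 (-0.93), ADM (-1.95), PDK1 (-0.40) and the glucose carrier SLC2A3 (-2.21). SLC2A3 was at 22.9, 37.5 and 4.19 CPM in control libraries 1, 2 and 3 and at 4.6 to 4.68 CPM with palbociclib, so that its fall rested on control libraries 1 and 2. ADM was low throughout, at 1.16, 1.48 and 0.415 CPM in these control libraries.

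Lysosome and autophagy genes were higher in 31 of 41 and lower in 4, or 32 and 6 when adjusted over the list alone. Their median was 0.46 (camera adjusted p = 5.19e-08, and adjusted p = 0.115 with an estimated correlation). Proton pump subunits ATP6V0E1 (0.94) and ATP6V1A (0.71) and the saposin precursor PSAP (734.6 ± 41.2 to 1293 ± 30.2 CPM, 0.82) were among them, and MAP1LC3B, an autophagosome protein, fell (-0.67). Nuclear genes of oxidative phosphorylation rose in 30 of 50 and fell in 1, or 32 and 2 when adjusted over the list alone. Their median was 0.22, or 0.11 with library size alone (camera adjusted p = 9.39e-06, and adjusted p = 0.172 with an estimated correlation). The complex I subunit NDUFV2 (0.69) and the ATP synthase subunit ATP5PB (0.46) rose. Mitochondrially encoded transcripts rose in 13 of 15, 14 when adjusted over the list alone (median 0.44, camera adjusted p = 1.07e-05, adjusted p = 0.369 with an estimated correlation). Their share of counts was 5.67% to 6.15% in controls and 7.05% to 7.43% with palbociclib, and MT-CO1 went from 14110 to 20020 CPM (0.50). Its call was lost on log2(FPKM + 1) (adjusted p = 0.163, range 1.41e-50 to 0.163) and on log2(FPKM + 0.1) (0.112), at 0.40 on both.

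**Figure D3:**
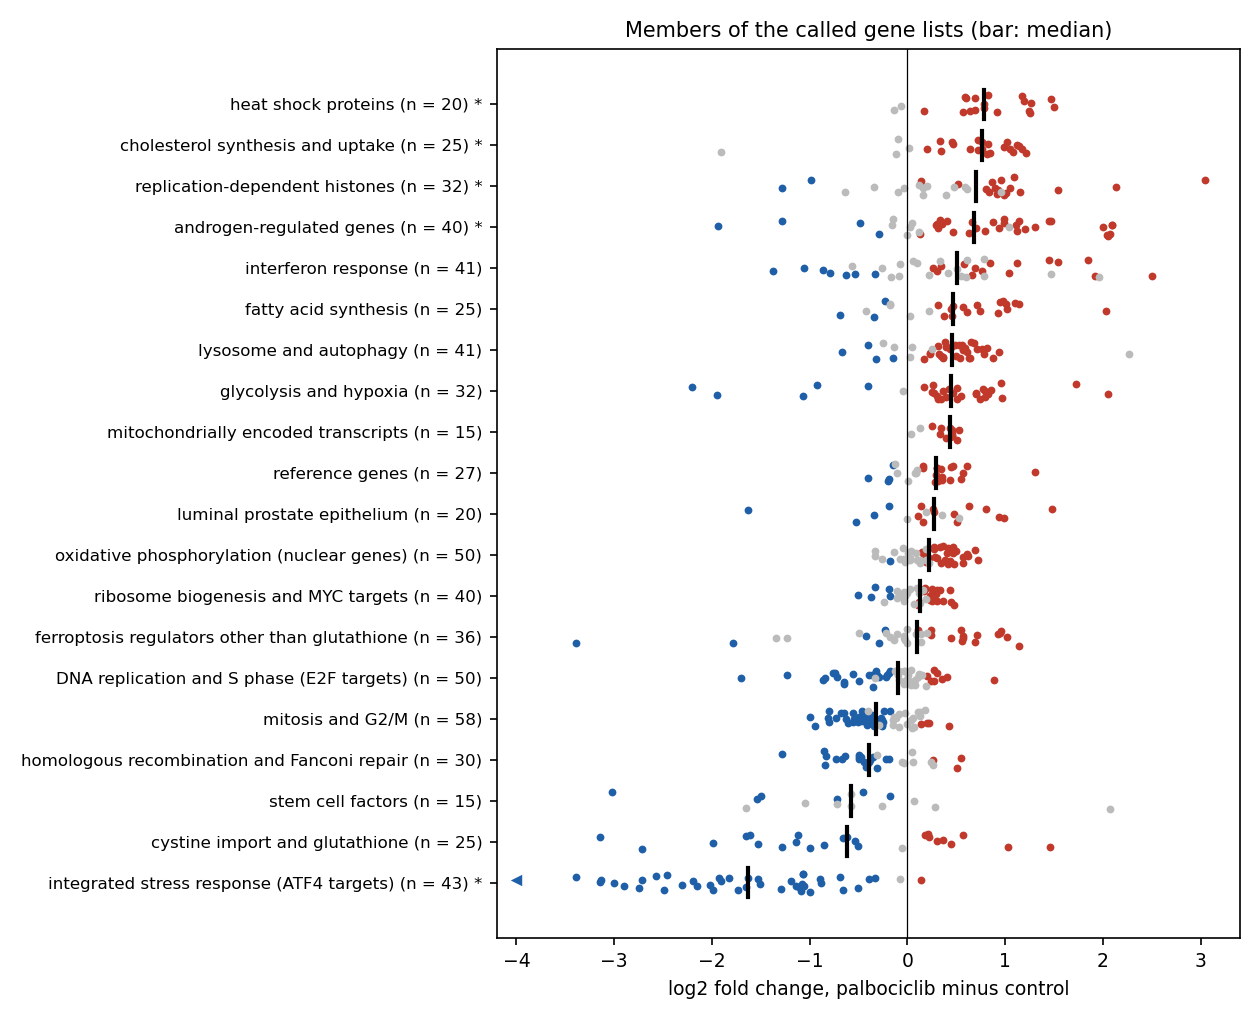
Log2 fold change, palbociclib minus control (horizontal axis), of each tested member of the 20 lists called by camera, with n tested members per list; red and blue points passed the edgeR threshold, grey points did not, black bars are medians and 1 point drawn as a triangle lies beyond the left edge. Asterisks mark the 5 lists also called with an estimated correlation, and the ATF4 targets lie farthest from 0.

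Mitosis and G2/M genes fell in 36 of 58 and rose in 4, or 37 and 5 when adjusted over the list alone. Their median was -0.32 (camera adjusted p = 1.92e-06, and adjusted p = 0.115 with an estimated correlation). The mitotic transcription factors FOXM1 (143.8 ± 5.59 to 82.3 ± 2.77 CPM, -0.80) and MYBL2 (-0.95), the anaphase activator CDC20 (-0.55) and the kinesin KIF2C (-0.73) were lower. Homologous recombination and Fanconi genes fell in 20 of 30 and rose in 3, or 20 and 4 when adjusted over the list alone. Their median was -0.39 (camera adjusted p = 0.000276, and adjusted p = 0.126 with an estimated correlation). Among those that fell were EXO1 (-1.28), BRCA1 (-0.85), BARD1 (-0.84) and the checkpoint kinase CHEK1 (-0.83). Among 50 DNA replication genes 22 fell and 8 rose, or 23 and 8 when adjusted over the list alone. Their median was -0.09 (camera adjusted p = 0.035, and adjusted p = 0.172 with an estimated correlation). The primase subunits went opposite ways, PRIM1 by -1.23 and PRIM2 by 0.88, and ribonucleotide reductase RRM2 (-0.65) and the helicase subunit MCM7 (-0.56) fell. PCNA (-0.03) and MCM2 (-0.01) did not pass. The median was -0.20 with library size alone and -0.02 with overlapping exons left out (adjusted p = 0.64). The call was also lost against control library 3 alone (0.079) or when control library 2 (0.0602), palbociclib library 1 (0.0714) or palbociclib library 2 (0.0719) was left out, and over alternatives its adjusted p ran from 0.000499 to 0.64.

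Cyclins, CDKs, their inhibitors and the RB/E2F family gave no list call, with 7 higher, 13 lower of 30, the same when adjusted over the list alone. Their median was -0.04 (camera adjusted p = 0.216). Leaving out genes with overlapping exons moved the median to -0.64 (adjusted p = 0.0172, range 0.000352 to 0.369). The repressor E2F7 (-1.43), the RB relative RBL1 (-0.77) and the CDK inhibitor CDKN1B (-0.91) fell. Replication-dependent histone genes rose in 17 of 32 and fell in 2, or 18 and 2 when adjusted over the list alone. Their median was 0.70 (camera adjusted p = 2.83e-05, and adjusted p = 0.0486 with an estimated correlation). H2BC21 went from 157 ± 4.71 to 458.5 ± 14.3 CPM (1.55), the linker histone H1-2 from 250.7 to 475.3 CPM (0.92), H4C8 rose by 1.15, and the exceptions were H2BC17 (-1.28) and H2AC20 (-0.99). Members of this family are near-identical in sequence, so that the division of reads between them is uncertain.

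Cytosolic ribosomal protein genes mostly did not pass, with 4 higher and 15 lower of 73, or 4 and 13 when adjusted over the list alone. Their median was -0.0036 (camera adjusted p = 0.508). Their list was lower with library size alone (median -0.12, adjusted p = 0.0178, range 0.00508 to 0.998), against control library 3 alone (-0.11, adjusted p = 0.0129), on log2(FPKM + 1) (0.00508) and on log2(FPKM + 0.1) (0.0222). The median was above 0 with RLE factors. RPL10 (-0.47), RPS2 (-0.38), RPS16 (-0.30) and RPL13 (1061 ± 179 to 321.4 ± 116 CPM, -1.72 ± 0.24) fell, all members of a family with many processed pseudogenes. Ribosome biogenesis genes rose in 19 and fell in 5 of 40, or 22 and 6 when adjusted over the list alone. Their median was 0.13 (camera adjusted p = 0.035, and adjusted p = 0.418 with an estimated correlation). Nucleolin, NCL (0.44), and NOLC1 (0.45) rose, and ODC1 (-0.33) fell. With library size alone that median was 0.02 (adjusted p = 0.308, range 0.00305 to 0.418), and the call also ended with DESeq2 (0.0543), counts divided by 4 (0.0759), a minimum count of 40 (0.0752), overlapping exons left out (0.302) or control library 3 as the single control (0.0793). The 27 reference genes commonly taken as constant rose in 17 cases and fell in 4, also when adjusted over the list alone. Their median was 0.29 (camera adjusted p = 0.00084, and adjusted p = 0.172 with an estimated correlation). It was 0.18 with library size alone and 0.15 with overlapping exons left out. Medians of luminal genes (0.27), nuclear oxidative phosphorylation (0.22), ribosome biogenesis (0.13) and other ferroptosis regulators (0.10) were below 0.29. Those rises were therefore no larger than that of genes taken as constant. Camera compares a list with all tested genes. Called protein-coding genes leaned higher (3836 higher, 3154 lower) and long non-coding RNA genes lower (258 higher, 560 lower).

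Interferon response genes were higher in 16 of 41 and lower in 7, or 18 and 7 when adjusted over the list alone. Their median was 0.51 (camera adjusted p = 0.00302, and adjusted p = 0.095 with an estimated correlation). The transcription factor STAT2 (0.76), the ubiquitin-like ISG15 (26.6 ± 3.30 to 54.9 ± 2.65 CPM, 1.04) and IFITM3 (0.58) rose, GBP2 rose from a low level (0.746 to 4.23 CPM, 2.51), and PARP14 (-1.37) and IRF1 (-0.63) fell. Antigen presentation by MHC class I gave no call (8 higher, 5 lower of 23, the same when adjusted over the list alone; median 0.06, or -0.05 with library size alone, camera adjusted p = 0.472), although B2M (0.57), PSME2 (0.66) and PDIA3 (0.35) rose. NF-kB targets gave none either, with 2 higher, 7 lower of 18, the same when adjusted over the list alone. Their median was -0.33 (camera adjusted p = 0.123), although NFKB2 rose (0.75), and the list passed without control library 3 (adjusted p = 0.0251, range 0.0251 to 0.479). Against control library 3 alone the median was -0.06 (adjusted p = 0.479). Immediate early genes were at a median of -0.26 (4 higher, 6 lower of 24, the same when adjusted over the list alone; camera adjusted p = 0.484), with a rise of the phosphatase DUSP2 (1.52) and a fall of ATF3 (-2.19), which ATF4 also induces. Against control library 3 alone that median turned to 0.03, with 2 higher and 2 lower of 25.

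Lists of cell identity held many low genes, and control libraries 1 and 2 shared transcripts that were lower in control library 3. With at least 40 counts in both, 223 genes were at 3 or more times the level of control library 3. Of these, 88 were called lower and 2 higher with palbociclib. Stem cell factors were lower in 6 of 15 and higher in 0, also when adjusted over the list alone (median -0.58, camera adjusted p = 0.035, adjusted p = 0.556 with an estimated correlation), led by BMI1 (-0.45), ITGA2 (-0.72), KLF4 (-1.54) and PROM1 (-3.02). PROM1 was at -1.23 against control library 3 alone (adjusted p = 0.303, range 2.44e-06 to 0.303). Against that library the list's median was -0.02 (adjusted p = 0.708, range 0.0024 to 0.708), and the call also ended with library size alone (0.0745), with DESeq2 (0.0543) and without control library 1 (0.0691), control library 2 (0.125), palbociclib library 1 (0.0731) or palbociclib library 2 (0.0518). Factors secreted by senescent cells gave no call, with 5 higher, 7 lower of 25, or 5 and 8 when adjusted over the list alone. Their median was -0.80 (camera adjusted p = 0.367), and against control library 3 alone the median was 0.18. IGFBP5 (2.96) and IGFBP3 (13.7 ± 2.21 to 76.1 ± 0.606 CPM, 2.47) rose, and VEGFA and GDF15 fell. By fry the same list was not called either, and its upward direction (fry adjusted p = 0.749) shows no rise.

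Neuroendocrine genes had 1 higher and 3 lower of 15, the same when adjusted over the list alone (median -0.59, camera adjusted p = 0.18), and passed without control library 3 (adjusted p = 0.0174, range 0.0142 to 0.379) and with no filter on low counts (0.0149), where the median was -1.53. Without palbociclib libraries 1, 2 and 3 in turn that median was -0.96, -1.06 and -1.09, with no call. EZH2, a Polycomb methyltransferase raised in that state, fell from 92.8 ± 0.95 to 28.3 ± 1.86 CPM (-1.71), ENO2 (-0.93) and PEG10 (-1.68) fell, and the neuronal tubulin TUBB3 rose (1.67); PEG10 was at -0.23 against control library 3 alone (adjusted p = 0.399, range 1.82e-05 to 0.399). Epithelial-mesenchymal transition genes gave no call, with 3 higher, 6 lower of 20, or 3 and 7 when adjusted over the list alone. Their median was -0.45 (camera adjusted p = 0.367), and the list passed without control library 3 (adjusted p = 0.0283, range 0.0283 to 0.833). Fibronectin, FN1, fell from 607 ± 188 to 282.9 ± 24.5 CPM (-1.10) and thrombospondin, THBS1, by 0.98 log2 units. Against control library 3 alone FN1 was at -0.53 and still passed (adjusted p from 3.81e-05 to 0.014 over its alternatives). Basal epithelial genes had 3 higher and 4 lower of 13, the same when adjusted over the list alone (median -0.59, camera adjusted p = 0.488), with a rise of annexin ANXA1 (1.60) and a fall of the integrin chain ITGA6 (-0.59). Against control library 3 alone the medians of the last 3 lists were -0.30, 0.10 and 0.06. Markers of stroma had 2 higher and 1 lower of 11, or 1 and 1 when adjusted over the list alone (median 0.04, mean -0.21, -0.07 with library size alone, camera adjusted p = 0.885). Markers of blood and endothelium had 2 higher and 2 lower of 13, or 1 and 2 when adjusted over the list alone (median -0.91, although camera's direction was upward, camera adjusted p = 0.836; median 1.24 against control library 3 alone). FBLN1, a stromal matrix gene, was at 5.42 ± 4.10 and 0.749 ± 0.413 CPM and PTPRC, the leukocyte antigen CD45, at 1.19 ± 0.544 and 0.47 ± 0.111 CPM, and both were called lower. Other markers of blood and endothelium went both ways: over the alternatives CD68 lay at 0.77 to 1.54 and VWF at -1.105 to -0.472. The call of FBLN1 ended against control library 3 alone (adjusted p = 0.551, range 0.000539 to 0.551). That of PTPRC ended against control library 3 alone (adjusted p = 0.234, range 0.0159 to 0.234) and without control library 2 (0.116), palbociclib library 1 (0.0822) or palbociclib library 2 (0.0807).

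Reads of genes that overlap on opposite strands or have near-identical copies could not be told apart here. In simulated data with a spread drawn per gene, 10.2% of edgeR's calls were false, above the nominal 5%. With a spread that followed the expression trend, 4.12% were false. Each simulated set had only 200 changed genes, whereas 38.6% of tested genes were called here. Those shares of false calls need not hold for the real calls.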

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

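Tests chosen only after the data were seen were those with counts divided by 4, a minimum count of 40, control library 3 as the single control, mitochondrially encoded genes left out and genes with overlapping exons left out. Of 2572 values recomputed for the 138 genes that the rule named and that are reported here, 2523 kept direction and call, 49 lost the call, 0 gained it and 0 reversed. Of 734 values for 35 lists, 679 kept direction and call, 40 lost it, 15 gained it and 0 reversed. Genes called with the main settings were also called for 99.56% with RLE factors, 98.78% with DESeq2, 85.64% with library size alone and 58.88% with control library 3 as the single control.

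The main settings called 4270 genes higher and 3921 lower. Without control libraries 1 and 2, with fewer libraries and 23234 genes tested, 3022 were higher and 2182 lower, and 4823 of the 8191 calls were shared. Leaving out genes with overlapping exons gave 2694 and 2569 among 13353 genes tested. An unadjusted p under 0.05 with a fold above 2 gave 759 and 1379, an adjusted p under 0.05 with that fold 636 and 1118, and an adjusted p under 0.01 gave 3086 and 2449. Leaving out each library in turn gave 3605 to 4233 higher and 3057 to 3766 lower genes, and 13 to 14 higher and 4 to 9 lower lists. Camera called 14 lists higher and 6 lower, camera with an estimated correlation 4 and 1, and fry 16 and 10, including lists that camera did not call. Fry and no other alternative added p53 targets (adjusted p = 0.00228), unfolded protein response (0.00511), MHC class I (0.0274) and iron genes (0.0474); it also called cyclins (0.000352) and neuroendocrine genes (0.0142), and it does not compare a list with other genes. With the replicate block 3855 genes were higher and 3438 lower, and 13 and 5 lists. Deviations of libraries with the same number did not go together (correlations -0.00794, -0.0341 and -0.0311), so nothing here shows them to be paired. The block ended the list calls of DNA replication (camera adjusted p = 0.0571) and other ferroptosis regulators (0.0727). It also ended the gene call of PTPRC (edgeR adjusted p = 0.0583). The calls of GPX4, CDK4, PTPRC, MT-CO1, stem cell factors and ribosome biogenesis also ended on both FPKM scales, and those of SERPINA1, PEG10, PROM1 and FBLN1 on log2(FPKM + 1). The FPKM fits had no composition factor either, so they are not independent of library size alone. GPX4 was at 0.1111 with library size alone and at 0.1095 and 0.1105 on the FPKM scales. CDK4 was at 0.076, 0.078 and 0.079 in these settings. The medians of iron genes, stromal markers and cytosolic ribosomal proteins, which lay near 0, changed sign when some single libraries were left out. The causes of these differences were not tested unless given. Depth limits what can be said of genes near 12 counts, such as SOX2.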

Other observations

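The tests of control library 3 as the single control, of liver transcripts and of S phase were chosen only after the results were seen, and so were the annotation terms described first. RBCK1, ZCCHC3, SOX12, NRSN2, APOA1, VIL1 and ALB were also chosen after their values were seen. Among 308 annotation terms of 15 to 300 genes in the deposited table, camera called 40 higher and 1 lower. With an estimated correlation it called 0 either way. The reference genes had a median of 0.29, above that of several terms called higher. Proteasome subunits, which degrade ubiquitin-tagged proteins, were higher in 29 of 43 cases and lower in 3 (median 0.20, camera adjusted p = 2.24e-05, and adjusted p = 0.471 with an estimated correlation). The core subunit PSMA4 rose by 0.74 and the base subunits PSMD2 and PSMD1 by 0.58 and 0.52. Citrate cycle genes were higher in 20 of 28 and lower in 1 (median 0.33, camera adjusted p = 3.79e-05, and adjusted p = 0.56 with an estimated correlation). OGDH (0.59), IDH1 (0.45) and ACLY (0.74), which turns citrate into acetyl-CoA, rose, and PCK2 (-2.49) fell.

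Genes of valine, leucine and isoleucine degradation were higher in 32 of 46 and lower in 8 (median 0.33, camera adjusted p = 0.000129, and adjusted p = 0.471 with an estimated correlation). ECHS1, a mitochondrial enoyl-CoA hydratase, rose by 0.76, whereas BCAT1, a cytosolic branched-chain aminotransferase, fell (-2.63). Peroxisome genes were higher in 35 of 78 and lower in 6 (median 0.22, camera adjusted p = 0.000485, and adjusted p = 0.471 with an estimated correlation), among them CROT (1.01), ACAA1 (1.09) and ACSL3 (1.15). Neighbours of TRIB3 on chromosome 20 went different ways: RBCK1 (-1.07) and ZCCHC3 (-0.43) fell, and SOX12 (0.26) and DEFB132 (3.13) rose. NRSN2 was at 0.07 (edgeR adjusted p = 0.342).

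With 3 libraries against 3 there are 10 splits, so the share of splits as large as the real one is never under 0.1. The real split, 1 of the 10, called 8191 genes and the highest other split 0 by edgeR, with 161 to 588 genes at an unadjusted p under 0.05. Each other split puts libraries of both groups on either side, so that the difference between the groups adds to the spread. Few calls were therefore likely there. The contrast cannot tell palbociclib from another difference between the groups. For lists, 1 of the 10 splits reached the real value of 20, and the others gave 8 to 13. Camera at the preset correlation thus called lists where the groups were mixed. The sides of each mixed split hold unequal numbers of control libraries, so part of the difference between the groups stays. Those list calls therefore cannot show how far camera's small p-values overstate the evidence. With an estimated correlation the real split gave 5 lists and the others 0. Since the mixed groups add to the spread, that 0 does not show the 5 to be free of false calls.

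The fall of the ATF4 targets (median -1.63) was set against 3 technical explanations. Removing a trend on GC content and transcript length, known for 43 of 43 members, left a median of -1.50 (quartiles -2.14 and -0.96), although it removed 0.803% of the variance of all genes. With library size alone the median was -1.74, and against control library 3 alone it was -1.60, so that neither scaling nor transcripts of control libraries 1 and 2 account for it. In 41 of 43 members every palbociclib library lay below every control library. Palbociclib itself, the difference that the design names, stays open as a hypothesis, and ATF4 activity was not measured.

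Control libraries 1 and 2 shared 223 genes with at least 40 counts in both and 3 or more times their level in control library 3. Examples were APOA1 (16.8, 23.4 and 2.85 CPM) and VIL1 (9.84, 14.1 and 2.30 CPM). The other choices of 1 low library gave at most 54 genes, which argues against counting noise. RNA of liver cells would bring albumin, but the excess of ALB was 3.74% of that of APOA1, although 10 of 16 liver, 4 of 12 intestinal, 1 of 11 kidney and 2 of 12 mesenchymal markers were among the genes; control library 3 itself held 6, 2, 5 and 11 of these markers above 1 CPM. The interquartile range of the log2 ratio of the excess between both libraries was 0.669, between the bounds set for a single source and for several. Over the 91 genes that were also low in every palbociclib library it was 0.544, again between these bounds. A shared source of RNA could therefore not be decided. No biological explanation was tested.

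Replication-dependent histone transcripts rose (median 0.70, or 1.63-fold) while the libraries were selected for poly(A). Weaker selection in the palbociclib libraries was expected to raise small RNAs without a tail as much, and their share was 1.09 times that of controls. That share was only 0.00511% to 0.00631% of counts in any library. At so small a share the ratio cannot decide whether selection was weaker. More cells in S phase were expected to raise DNA replication genes, of which 8 rose and 22 fell of 50. The median of that list was only -0.09, and its members are E2F targets, which the drug's target pathway controls. They are therefore no independent measure of the share of cells in S phase, which was not decided. Polyadenylated histone transcripts, which cells that leave the cycle are known to make, cannot be counted apart here, and that explanation was not tested. Reads divided among near-identical histone genes were not tested as a cause.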
